A study of Mus musculus with 12 samples.

How the data were processed

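RNA sequencing was carried out on mouse acute myeloid leukaemia cells that carry the MLL-AF9 fusion, a product of a chromosome translocation found in acute leukaemia. Per the labels, 12 samples fell into 4 groups of 3. Cells with loxP-flanked Riok2 alleles (Riok2fl/fl) received ethanol (EtOH) or hydroxytamoxifen (OHT), and MLL-AF9 cells received DMSO or a RIOK2 inhibitor at 1 µM, each for 72 h. RNA was purified on silica columns and made into TruSeq libraries, per the labels' protocols. Per the submitters' processing notes, the tools were Trimmomatic 0.38.0, STAR 2.7.2b, HTSeq 0.9.1, DESeq and DESeq2, and the genome build was mm10. The gene annotation and the counting options, strand included, are not given in the sources used here.

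The values came from 1 table of the authors' own comparison, with 24221 rows and no named columns beyond numbers. The authors deposited for each gene a base mean, a signal in normalised reads averaged over libraries, and a log2 fold change with its standard error, also on the log2 scale. The next deposited columns are a Wald score, a p-value and an adjusted p-value. These identities were checked on the values: the deposited score equalled the fold change divided by its standard error to within 7.6e-08, and the deposited adjusted p-value equalled a Benjamini-Hochberg adjustment over 13814 genes to within 2.3e-07. The standard errors in the authors' deposited table do not exceed 0.747 even for genes with 1 read. The deposited log2 fold changes are therefore taken to be pulled towards 0 by a prior. They then understate the change of low genes, and also that of abundant genes with errors near this limit. An example in the authors' deposited table is Chil3 (base mean 86218, SE 0.747). The table does not say which group is the numerator. Riok2 has a negative deposited fold change, and all folds are therefore read as OHT over EtOH, a reading that rests on the targeted gene. The table has 0 columns of values per sample. The DMSO and RIOK2 inhibitor samples, and the difference between the 2 arms, are not analysed here.

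Before the data were examined, 3 forms of the main test were fixed, for counts, for normalised values and for a comparison table only. The last applied, so no test of the samples was made here, and the authors' adjusted p-value under 0.05 was the threshold throughout. Of the 24221 rows, 6693 had a base mean of 0, 3663 with a base mean of at most 1.94 had a p-value and no adjusted p-value, and 51 had a fold change and no p-value. The 27 gene names that a spreadsheet had turned into dates (22 tested, 12 past the threshold) were counted and not named. Of the names, 23264 were current symbols, 834 were older symbols and 123 matched neither.

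Reads per library were recovered from low base means. The smallest base means were sums of 6 steps, each 1 read in 1 library, which gave 6 libraries and their size factors. All 4645 genes with a base mean above 0 and at most 5 had exactly 1 solution in whole reads within a tolerance of 5e-09. On 2843 simulated genes 100% were solved correctly. The libraries cannot be matched to sample names and were not averaged or tested as groups. Ratios between 2 single libraries carry exact binomial intervals, which cover counting error only. The sign of the deposited fold change of genes with 1 read showed on which side of the comparison each library lay.

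The 30 gene lists were fixed before the data were examined. A list with at least 5 tested members was tested two-sided with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited score, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists tested. Medians and median standard errors were set against 10000 random lists matched on base mean in 20 bins. Members that passed were counted at the authors' adjusted p-value and with their p-values adjusted over the list alone. The test was tried on 100 simulated tables of the same 13814 genes. Each gene's fold was drawn independently there, so the rates below do not cover lists whose members move together. With a first set of shifts on the log2 scale, 0.25 in the ribosomal protein list was recovered in 41% of runs, 0.5 in the p53 list in 92% and 0.5 in the cholesterol list in 43%, and lists with no shift had an unadjusted p under 0.05 in 2.64%. A second set was added after these had been seen: 0.5 in the ribosomal protein list was recovered in 100%, 0.5 in the p53 list in 94% and 1 in the cholesterol list in 100%, with 2.59% for lists with no shift.

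Gene positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, the assembly that mm10 names. A length was found for 12538 tested genes (90.8%), and lists were compared with the 50 genes nearest to each member in base mean, length and GC content. The named genes follow a rule fixed before the data were examined: Riok2, the 10 largest rises and 10 largest falls past the threshold at a base mean of at least 100 (clone-style names left out), and for each list the 4 members with the smallest adjusted p-value and the member with the highest base mean. Members named outside this rule are said to be so. Some members that the rule names are not reported here. Alternatives covered the threshold, a minimum fold, the filter on low values, centring, Bonferroni adjustment and the settings of the list test. After seeing the data, genes with a standard error above 0.5 and members shared between lists were also left out in turn. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used.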

Results

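MLL-AF9 leukaemia cells with floxed Riok2 alleles were profiled 72 h after OHT or its vehicle EtOH, with 3 samples in each group. OHT activates tamoxifen-dependent Cre recombinases, and RIOK2 is an atypical kinase that acts in the cytoplasmic maturation of the small ribosomal subunit. Base means summed to 20307732 normalised reads per library over all genes in the authors' deposited table. The 6 library size factors recovered from the low base means were 1.88, 1.01 and 0.697 on the side where the authors' fold was above 0 and 1.11, 0.870 and 0.783 on the other side. For the 9915 genes with a base mean of at least 100, the median standard error in the authors' deposited table was 0.18 on the log2 scale. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

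The first question was how the transcriptome differed between OHT and EtOH. Riok2 (ENSMUSG00000116564.1, GRCm38 chromosome 17, 17374309 to 17394899, plus strand, protein coding) had a base mean of 712 and a log2 fold change of -3.60 ± 0.20 (authors' SE) in the authors' deposited table (adjusted p = 7.8e-69). Its level in OHT was 8.25% of that in EtOH, with a 95% interval of 6.28 to 10.8% from the standard error in the authors' deposited table. The exons removed from the floxed allele are not given in the sources used here. Of the 13814 genes tested in the authors' deposited table, 6752 (48.9%) passed the threshold, 3521 higher and 3231 lower in OHT. With genes of a standard error above 0.5 left out, a choice made after seeing the data, 3133 were higher and 3173 lower.

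Among genes with a base mean of at least 100, the steepest rise was that of Gpnmb, a glycoprotein of macrophages, with a log2 fold change of 4.65 ± 0.49 (SE, adjusted p = 1.4e-19) in the authors' deposited table. Next among these genes in the authors' deposited table came the formyl peptide receptor Fpr1 (4.45 ± 0.38), the scavenger receptor Msr1 (4.39 ± 0.29), the apoptotic cell receptor Mertk (4.17 ± 0.38), the phagosomal metal transporter Slc11a1 (4.12 ± 0.31), the C-type lectin Clec4n (4.05 ± 0.23) and the scavenger receptor Marco (4.02 ± 0.66). Cyp4a12a, which has near-identical copies and is uncertain, rose by 4.26 ± 0.43, Kcnn3 by 4.16 ± 0.44 and Plxdc2 by 3.94 ± 0.32 in the authors' deposited table. Among the falls at the same minimum in the authors' deposited table, Cth, which makes cysteine from cystathionine, had a log2 fold change of -5.08 ± 0.30 (SE, adjusted p = 1.3e-59). Further falls in the authors' deposited table were Myl10 (-4.81 ± 0.37), the folate enzyme Aldh1l2 (-3.66 ± 0.39), the secreted glycoprotein Stc2 (-3.57 ± 0.29), the ATP-gated channel P2rx3 (-3.12 ± 0.36), the branched-chain aminotransferase Bcat1 (-3.07 ± 0.47), the amino acid transporter Slc1a4 (-3.00 ± 0.24), Cdr2l (-2.93 ± 0.47) and the pseudokinase Trib3 (-2.78 ± 0.60).

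**Figure D1:**
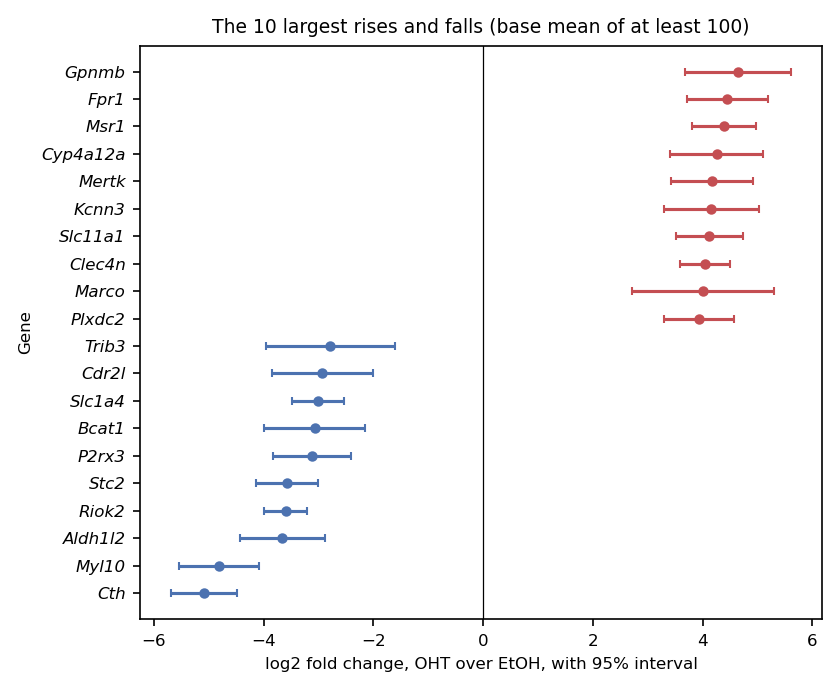
Log2 fold change of OHT over EtOH (x axis) for the 10 largest rises and 10 largest falls at a base mean of at least 100, from the authors' deposited table. Points are the fold changes, bars are 95% intervals from the authors' standard errors, and the values run from -5.08 for Cth to 4.65 for Gpnmb.

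**Figure D2:**
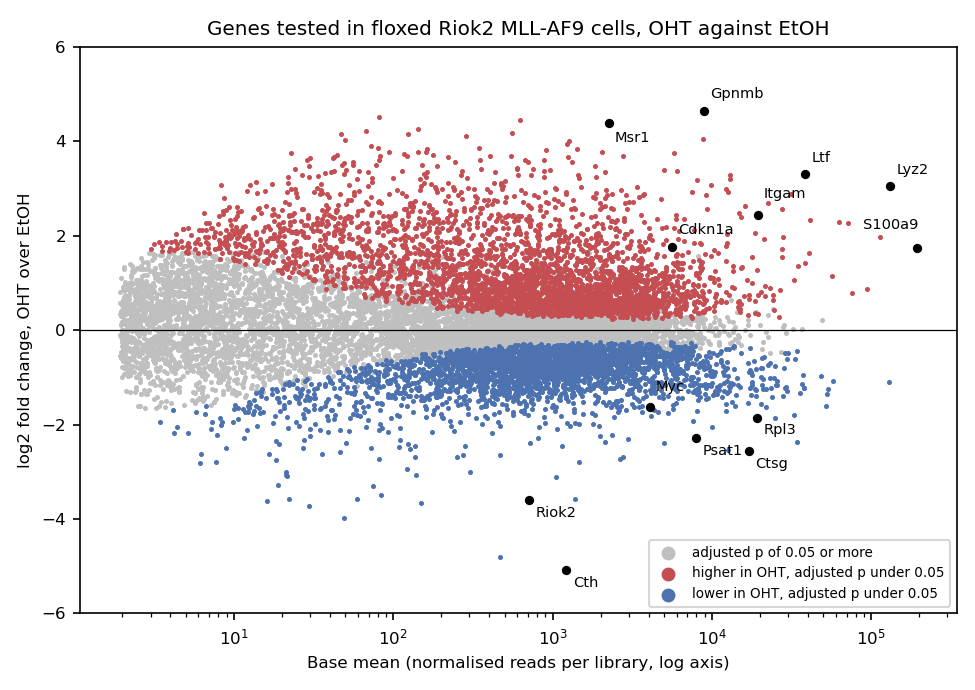
Base mean (x axis, log scale) against log2 fold change of OHT over EtOH (y axis) for the 13814 genes tested in the authors' deposited table. Red points passed the threshold higher in OHT (3521), blue points lower in OHT (3231), grey points did not pass, and black points carry their gene names, of which Riok2 sits at -3.60.

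Neutrophil and monocyte maturation genes rose in OHT, and several granule protease genes fell. Of 33 neutrophil maturation genes tested, 31 rose and 0 fell, also 31 and 0 when adjusted over the list alone, with a median log2 fold change of 2.21 (camera adjusted p = 1.6e-26). Examples in the authors' deposited table are the integrin Itgam (2.44 ± 0.12 SE), the gelatinase Mmp9 (3.37 ± 0.22), the secondary granule protein Ltf (3.31 ± 0.24), Ceacam10 (2.80 ± 0.19) and S100a9 (1.75 ± 0.17), which had the highest base mean of all genes at 194012. Of 47 monocyte and macrophage genes, 41 rose and 2 fell (42 and 2 adjusted over the list alone), with a median of 2.32 (camera adjusted p = 1.6e-17). They include, in the authors' deposited table, the CSF1 receptor Csf1r (2.96 ± 0.20), Emr1 (2.85 ± 0.19), which encodes the F4/80 antigen, Cd68 (2.32 ± 0.16), Msr1 and the lysozyme gene Lyz2 (3.05 ± 0.55). The 2 that fell, named after their values were seen, were Ly6c2 (-0.57 ± 0.17), uncertain because of near-identical copies, and Apoe (-0.70 ± 0.30) in the authors' deposited table. Among 19 primary granule and progenitor genes 9 fell and 3 rose, with the same counts adjusted over the list alone and a median of -0.47 (camera adjusted p = 5.9e-04), which lay within the central 95% of lists matched on base mean (-0.54 to 0.48). In the authors' deposited table the proteases Ctsg, Prtn3 and Elane fell by 2.56 ± 0.12, 1.79 ± 0.19 and 1.60 ± 0.17, and the peroxidase Mpo by 2.37 ± 0.23. The 3 that rose, named after their values were seen, were Ctsc (1.41 ± 0.18), Igsf6 (1.21 ± 0.18) and Hp (0.59 ± 0.19) in the authors' deposited table. Standard errors were wide in these genes for their base mean: the median was 0.24 for the neutrophil list and 0.34 for the monocyte list, above the upper limits of the central 95% of matched lists at 0.18 and 0.21. Whether 1 library contributed to these rises was not tested. In addition, 51 genes, among them Chil3 of the neutrophil list and Cd36, H2-Aa and H2-Ab1 of the monocyte list, had a fold change and no p-value in the authors' deposited table.

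Markers of other blood and tissue cells had fewer calls. Of 18 mast cell, basophil and eosinophil genes tested, 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.23). Their median of 0.67 lay above the central 95% of lists matched on base mean (-0.39 to 0.54), and the median standard error was 0.63 against an upper 95% limit of 0.25 in matched lists. That 1 was Ear2 (3.47 ± 0.45), a ribonuclease with near-identical copies and therefore uncertain, while Cpa3, the most abundant member, had 0.64 ± 0.62 (adjusted p = 0.41) in the authors' deposited table. Another 5 members, Ear1, Epx, Mcpt8, Prg2 and Prg3, had a fold change and no p-value there, so they could not be called. Of 23 erythroid and megakaryocyte genes, 7 rose and 0 fell, with a median of 0.93 (camera adjusted p = 0.041, and adjusted p = 0.14 with a preset correlation of 0.05). They include Vwf, the von Willebrand factor gene (3.82 ± 0.20), and Runx1 (0.89 ± 0.15) in the authors' deposited table. The median standard error of this list was 0.59, above the upper 95% limit of matched lists at 0.54, and its 5 low members had 43.0 normalised reads in the library with a size factor of 0.697 beside 3.20 and 3.95 in the others on its side. The 16 lymphoid and NK genes gave 4 higher and 3 lower (median -0.05, camera adjusted p = 0.59), with Lck at -2.49 ± 0.41 and Il7r at 2.38 ± 0.75 in the authors' deposited table. Without members of other lists, a choice made after seeing the data, the median was 0.050. The others, named after their values were seen, were Cd3d, Cd79a and Blnk among the higher and Cd79b and Rag2 among the lower. Of 11 stromal and endothelial genes 4 rose and 0 fell, 3 and 0 adjusted over the list alone (median 0.46, camera adjusted p = 0.17), led by the collagen gene Col5a1 (3.78 ± 0.36) and with Vim at 0.74 ± 0.15 in the authors' deposited table, and with Col1a1 and Acta2 as the others. The lymphoid and stromal lists also had wide errors, with median standard errors of 0.70 and 0.55 beside upper 95% limits of 0.67 and 0.52.

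Genes of the translation machinery fell together. All 78 cytosolic ribosomal protein genes tested were lower in OHT, also adjusted over the list alone, with a median log2 fold change of -1.19 and a range of -1.86 to -0.68 (camera adjusted p = 3.9e-29). In the authors' deposited table Rpl3 fell by 1.86 ± 0.13, Rpl10a by 1.72 ± 0.15, Rps2 by 1.62 ± 0.13 and Rpl4, the most abundant, by 1.24 ± 0.15. Ribosomal protein genes have many processed copies in the genome, and how reads were shared with these is not given in the sources used here. Of 46 factors for 40S maturation, 44 fell and 0 rose, and 1 rose and 44 fell adjusted over the list alone (median -0.80, camera adjusted p = 3.7e-15). The list is not limited to the cytoplasmic step in which RIOK2 acts. Rrp9 (-1.42 ± 0.12), Wdr43 (-1.45 ± 0.13) and the endonuclease Nob1 (-1.40 ± 0.13) fell in the authors' deposited table, and Riok3, a paralog of Riok2, stood at 0.35 ± 0.16 (adjusted p = 0.058). Of 57 factors of 60S assembly and the nucleolus 54 fell and 0 rose (55 and 0 adjusted over the list alone, median -1.15, camera adjusted p = 5.9e-28), with Npm3 at -1.79 ± 0.12 and nucleolin, Ncl, at -1.33 ± 0.19 in the authors' deposited table. Of 46 initiation and elongation factors 40 fell and 1 rose, also adjusted over the list alone (median -0.87, camera adjusted p = 2.6e-17). Pabpc4 (-1.58 ± 0.11) and Eef1a1 (-1.10 ± 0.16) were among those that fell in the authors' deposited table, and Eif4g3, named after its value was seen, rose by 0.46 ± 0.14. All 18 snoRNA host genes and other genes with a 5-prime TOP motif fell, also adjusted over the list alone (median -1.49, camera adjusted p = 1.4e-08), among them Snhg4 (-2.14 ± 0.29) and 1500012F01Rik, the older name of Zfas1 (-2.45 ± 0.32), in the authors' deposited table. The median standard errors of the ribosomal protein and snoRNA host lists, 0.19 and 0.27, lay above the upper 95% limits of matched lists at 0.17 and 0.21.

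Most listed targets of the transcription factors ATF4 and CHOP fell. Of 42 ATF4 and CHOP targets tested, 35 fell and 1 rose, also adjusted over the list alone, with a median of -1.58 (camera adjusted p = 8.1e-28). The serine synthesis enzymes Psat1 (-2.29 ± 0.11) and Phgdh (-2.72 ± 0.16), the mitochondrial folate enzyme Shmt2 (-2.39 ± 0.15) and Atf4 itself (-1.61 ± 0.14) fell in the authors' deposited table. The 1 that rose, named after its value was seen, was the cystine transporter Slc7a11 (0.84 ± 0.24) in the authors' deposited table. Their median standard error was 0.22, above the upper 95% limit of matched lists at 0.19. Among 25 endoplasmic reticulum chaperones and XBP1 targets 8 fell and 2 rose (median -0.32, camera adjusted p = 0.10), with Xbp1 at -0.67 ± 0.12 and Edem1 at 0.65 ± 0.16 in the authors' deposited table, where Dnajb9, named after its value was seen, rose by 0.59 ± 0.23. The median standard error of this chaperone list was 0.19, above the upper 95% limit of matched lists at 0.18.

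Targets of p53 rose. Of 38 tested, 29 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 1.12 (camera adjusted p = 1.4e-09). The cell cycle inhibitor Cdkn1a (1.77 ± 0.13), Trp53inp1 (2.80 ± 0.16), Btg2 (1.81 ± 0.15) and Ccng1 (1.27 ± 0.18) rose in the authors' deposited table, and Pmaip1, named after its value was seen, fell by 0.67 ± 0.20. Of 17 genes of the BCL2 family 7 rose and 2 fell (median 0.39, camera adjusted p = 0.23). In the authors' deposited table the anti-apoptotic Mcl1 (1.13 ± 0.15) and the pro-apoptotic Bcl2l11 (1.67 ± 0.23) and Bax (0.70 ± 0.12) rose, and Bid fell by 1.24 ± 0.12.

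Replication and growth genes fell, and the leukaemia programme list did not pass its test. Of 50 genes of G1/S and DNA replication 41 fell and 1 rose (42 and 1 adjusted over the list alone, median -0.73, camera adjusted p = 1.7e-13), among them the helicase subunit Mcm6 (-0.95 ± 0.09) and the origin recognition subunit Orc6 (-1.07 ± 0.11) in the authors' deposited table. Of 50 genes of G2/M and mitosis 26 fell and 2 rose (median -0.32, camera adjusted p = 4.1e-04), with the kinase Cdk1 at -0.67 ± 0.11 and Mki67, the most abundant, at 0.38 ± 0.19 (adjusted p = 0.082) in the authors' deposited table. Of 30 Myc targets and regulators 19 fell and 1 rose (median -1.03, camera adjusted p = 1.3e-10). Myc fell by 1.63 ± 0.11 and Impdh2, of guanine nucleotide synthesis, by 1.62 ± 0.11 in the authors' deposited table. Of 30 genes of the MLL-AF9 and stem programme 10 fell and 1 rose (median -0.23, camera adjusted p = 0.17). Myb (-0.87 ± 0.11), Mef2c (-1.14 ± 0.13) and Hoxa11 (-1.56 ± 0.21) fell and Id2 rose by 2.59 ± 0.14 in the authors' deposited table. Rises against the direction of the other lists, named after their values were seen, were E2f2 (0.91 ± 0.20) in G1/S, Kif23 (0.53 ± 0.16) and Aspm (0.54 ± 0.23) in mitosis and the Myc antagonist Mxd1 (1.54 ± 0.19) in the authors' deposited table.

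Inflammatory, interferon and immediate early genes rose. Of 34 NF-kB and inflammatory genes 25 rose and 0 fell, 28 and 0 adjusted over the list alone (median 1.66, camera adjusted p = 1.8e-08). The interleukin 1 antagonist Il1rn (2.89 ± 0.19), Tnfaip3 (2.31 ± 0.22), Nfkbia (1.76 ± 0.18) and the chemokine Ccl6 (2.88 ± 0.59) rose in the authors' deposited table. Of 47 interferon response genes 31 rose and 2 fell (median 0.87, camera adjusted p = 3.5e-06), including Ddx58 (1.82 ± 0.17), which encodes the RNA sensor RIG-I, and Slfn1 (2.83 ± 0.28) in the authors' deposited table. The 2 lower members, Psmb8 (-0.87 ± 0.14) and Gbp3 (-1.09 ± 0.24) in the authors' deposited table, were named after their values were seen. Of 29 immediate early genes 20 rose and 2 fell (median fold 2.84, camera adjusted p = 2.7e-08), among them Fos (3.57 ± 0.21) and Klf4 (2.35 ± 0.18) in the authors' deposited table, while Spry2 (-0.98 ± 0.26) and Dusp2 (-0.96 ± 0.31), named after their values were seen, fell. The median standard errors of the inflammatory and immediate early lists, 0.36 and 0.30, lay above the upper 95% limits of matched lists, both 0.24.

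Lysosomal genes rose and nuclear genes of oxidative phosphorylation fell. Of 37 lysosome and autophagy genes 28 rose and 1 fell (median 0.70, camera adjusted p = 9.8e-10), among them the saposin precursor Psap (2.27 ± 0.14), the cholesterol transporter Npc1 (1.65 ± 0.12), the protease Ctsd (2.34 ± 0.19) and Grn (1.25 ± 0.11) in the authors' deposited table, while Atg9b, named after its value was seen, fell by 1.84 ± 0.20. Of 49 nuclear oxidative phosphorylation genes 41 fell and 0 rose, 42 and 0 adjusted over the list alone (median -0.53, camera adjusted p = 4.4e-08), with Uqcrq at -1.34 ± 0.15 and Atp5b at -0.76 ± 0.13 in the authors' deposited table. That median lay within the range of genes matched on base mean, transcript length and GC content (-0.60 to -0.12), and just below it (-0.52 to -0.08) when translation and mitochondrial ribosomal genes were not drawn, a choice made after seeing the data. Of 23 glycolysis genes 10 fell and 4 rose (median -0.35, camera adjusted p = 0.089), with Tpi1 at -1.34 ± 0.13 and Pfkfb4 at 2.06 ± 0.22 in the authors' deposited table, and Ldhb, Slc2a3 and Hk3, named after their values were seen, as the other rises. The glycolysis median was 0.020 with members of other lists left out, a choice made after seeing the data. Of 25 cholesterol synthesis genes 2 fell and 0 rose, 1 and 0 adjusted over the list alone (median -0.22, camera adjusted p = 0.30). Acat2 had a log2 fold change of -1.03 ± 0.29 in the authors' deposited table. Of 11 oestrogen receptor targets, fixed because OHT binds that receptor, 5 rose and 4 fell (median 0.48, camera adjusted p = 0.23), with Ctsd and Ltf among the rises and Igfbp4 at -1.59 ± 0.14 in the authors' deposited table. The other rises were Rara, Ccnd1 and Nrip1 and the other falls Myb, Xbp1 and Greb1, named after their values were seen. Of 23 housekeeping reference genes 5 rose and 11 fell (median -0.35, camera adjusted p = 0.15), with Actb at 0.79 ± 0.17 and Gapdh at -0.75 ± 0.10 in the authors' deposited table. The other rises included B2m, and Reep5 and Rab7, named after their values were seen. Of the 15 mitochondrially encoded genes listed, 0 had their name in the table.

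**Figure D3:**
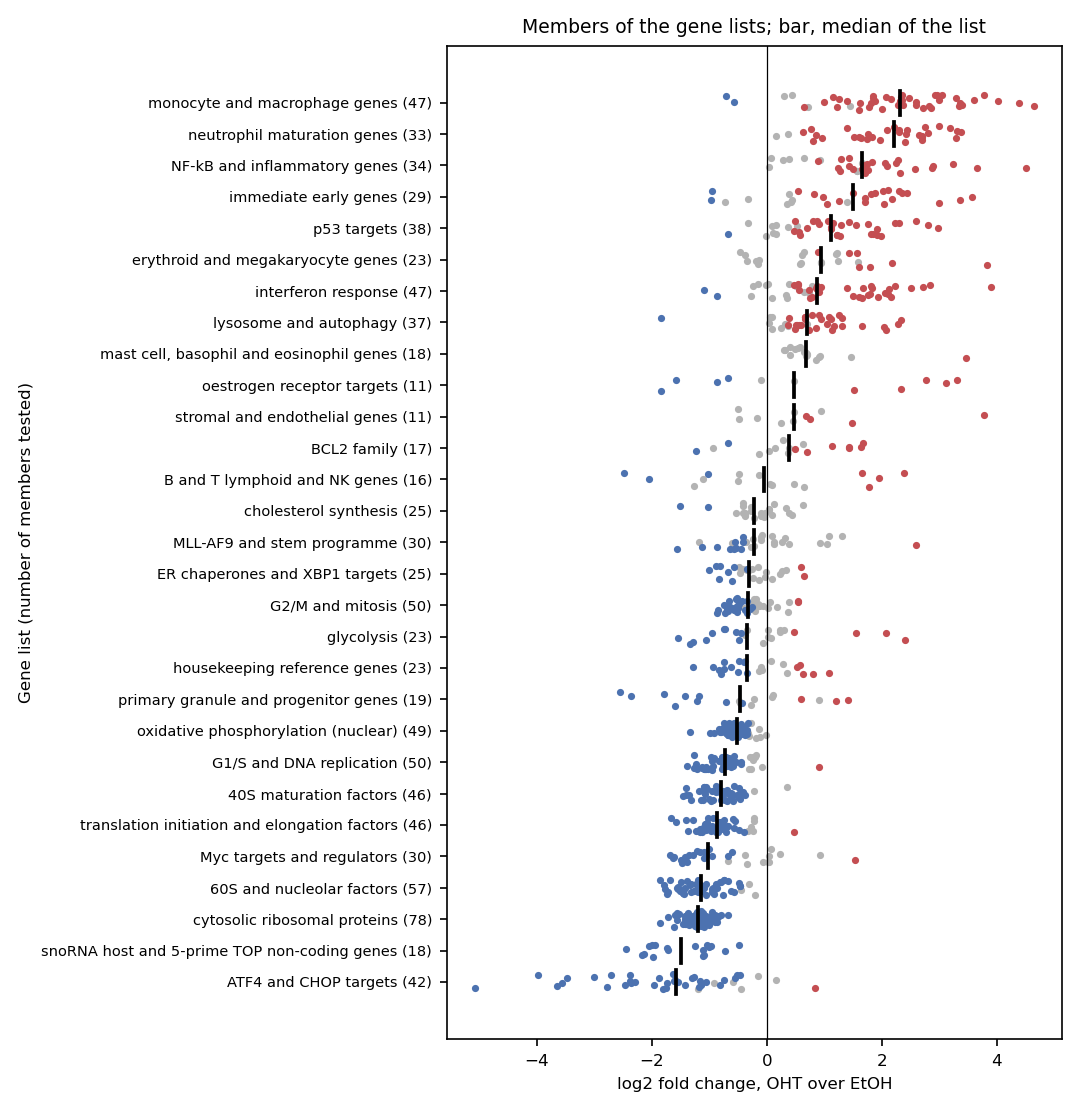
Log2 fold change of OHT over EtOH (x axis) of the tested members of 29 gene lists (y axis, number of members in brackets), from the authors' deposited table. Each point is a gene, red where it passed the threshold higher in OHT, blue where lower and grey where it did not pass, and black bars are list medians, which run from -1.58 to 2.32.

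Where no other count is given, the counts adjusted over the list alone equalled those over all genes tested. In total 19 of 29 lists passed the list test, 8 towards higher and 11 towards lower values in OHT, and 18 of these also passed with a preset correlation of 0.05. A correlation estimated from the samples could not be had without values per sample. The table holds no cells without floxed alleles given OHT, so the action of OHT itself and the loss of Riok2 were not separated. The comparison of the RIOK2 inhibitor with DMSO is not analysed here.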

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

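The tests of the size factor, of genomic DNA, of cells of other myeloid types and of library scaling were chosen only after the results they measure had been seen, as were the limits of 10 reads, 80% of reads and a base mean of 5. The other tests were written down before their results were computed.

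A set of values outside every comparison drew attention. There were 51 genes in the authors' deposited table that had a fold change and no p-value, with a median base mean of 131, well above the level at which genes were filtered, and 50 of the 51 folds were above 0. They include Chil3 (base mean 86218), Arg1 (3699), Mcpt8 (3144), Ccl24 (2908), Prg2 (2880) and Cd36 (2440) in the authors' deposited table. These names were chosen after their values were seen.

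Of the low genes, 1229 had at least 10 recovered reads, and 32 of these had over 80% of their normalised reads in the library with a size factor of 0.697, against 6 and 0 in the other libraries on its side and 0 in each library of the other side. With folds read as OHT over EtOH, that library lies on the OHT side. A size factor that is too small would raise every gene alike, but with it raised 1.53 times, so that the low genes summed to the same level as in the nearest library of its side, 19 such genes were left beside at most 6 in any other library, which argues against it as the whole cause of the 32. Genomic DNA remains open and cannot be told apart: olfactory and vomeronasal receptor genes were 1.33 times as high there as in one library of its side (95% interval 0.933 to 1.88, for counting error only) and 2.00 times as high as in the other (1.29 to 3.14), beside 1.53 and 1.56 for all low genes. Cells of other myeloid types may also contribute and cannot be told apart. The missing p-values of the 51 genes are taken to mark an extreme count in at least 1 sample. Whether the same library is extreme in all 51 genes, or which, is unknown. Of 21 mast cell, basophil and eosinophil markers, 5 were among those genes (Fisher's exact test, two-sided, adjusted p = 8.2e-07 over 30 lists). So were 3 of 48 monocyte and macrophage genes, Cd36, H2-Aa and H2-Ab1 (adjusted p = 0.019 by the same test). That test treats genes as independent, while markers of the same cells can move together, so both p-values may be too small. No biological explanation was tested, since the library carries no name.

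The fall of the ribosomal protein genes could come from a trend with transcript length, GC content or expression. Random lists from the nearest genes reached a median of -0.51 at the 2.5th percentile, above the -1.19 of the list, which argues against that trend as the whole cause, although the nearest genes had a median base mean of 5487 beside 12712 for the list. The scaling of the libraries cannot be told apart as a cause of the absolute fall: the median log2 fold change of genes with a base mean of at least 100 was -0.0192, but size factors set the typical gene near 0, and 1 scaling factor moves the list and other genes alike. Reads shared with processed copies, and a response of the OHT group to Riok2 loss or to OHT itself, stay open as untested.

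The rise of the p53 targets could rest on members that other lists also hold. The 31 members in no other list included 25 that rose and 0 that fell, and the 30 with a transcript length had a median of 1.18, above matched random lists (-0.32 to 0.38). Only 7 of the 38 tested members were shared with another list, so with 29 that rose this result was largely fixed in advance. It shows that the shared members were not the whole cause, and no more. It does not cover genes that change with myeloid maturation but are in none of those lists. Their part in the rise was not tested. A single library of the OHT group would widen the members' errors. The 38 tested members had a median standard error of 0.18, at percentile 46.3 of matched lists. That argues against 1 library as the cause in the typical member. Perp, also of this list, had a log2 fold change of 1.12 ± 0.74 (SE) and no p-value in the authors' deposited table. It lay outside that median. Among the lists that passed the list test, the neutrophil, monocyte, erythroid, primary granule, inflammatory, immediate early, ribosomal protein, snoRNA host and ATF4 lists had wide errors by the same measure. For those lists 1 library stays open as a contributor. A candidate explanation, as a hypothesis only, is a p53 response in the OHT group. Whether it follows Riok2 loss or OHT itself was not tested.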

How the results depend on the processing

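The alternatives that left out genes with a standard error above 0.5, or members shared between lists, were chosen only after the data were seen. Against 6752 genes in the main count (3521 higher, 3231 lower in OHT), a minimum of 2-fold left 2891 (1882 higher, 1009 lower, 65.1% higher beside 52.1%) and Bonferroni adjustment left 2865 (1529 higher, 1336 lower), both by construction stricter. The other settings stayed within 1.5 times the main count, from 2841 higher and 2322 lower at a minimum of 1.5-fold to 3608 and 3135 after centring. Of 158 recomputed values for 20 named genes 157 kept their direction and call, and Trib3 missed the Bonferroni threshold (adjusted p = 0.051). These genes were chosen as the largest changes past the threshold, and the settings reuse the same deposited folds and p-values. That count was therefore largely fixed in advance and says little about other genes. Marco (SE 0.66) and Trib3 (SE 0.60) had no value with genes of a standard error above 0.5 left out. Of 171 recomputed list results 165 kept their direction and call. These settings also reuse the same deposited folds and scores, so much of this count was fixed in advance. With shared members left out the median of 2 lists changed sign, glycolysis from -0.35 to 0.020 and B and T lymphoid and NK genes from -0.05 to 0.050, neither past the threshold (adjusted p = 0.66 for both). The erythroid and megakaryocyte list lost its call at a preset correlation of 0.05 (adjusted p = 0.14) and at a base mean of at least 100 (0.068), and 2 lists gained one: endoplasmic reticulum chaperones in the rank test (0.038) and mast cell, basophil and eosinophil genes with log2 fold changes (0.010). The cause was not tested. No paired analysis was possible because the table holds no values per sample. For the same reason another normalisation, other pseudocounts, leaving out each replicate, all groups in 1 fit, an estimated correlation and other splits of the 6 samples were not run, nor was any alternative for the inhibitor arm. The deposited folds are taken to be pulled towards 0 where errors are wide. The changes of genes with few reads, and of abundant genes with wide errors, may therefore be understated.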

Other observations

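Gene families picked by symbol after their values were seen are described here. Some hold genes of the lists above, such as Gars of the ATF4 list and S100a9 of the neutrophil list. They are therefore not separate evidence. Of 77 mitochondrial ribosomal protein genes 74 were lower and 0 higher in OHT, with a median log2 fold change of -0.80, below lists matched on base mean, length and GC content (-0.47 to -0.16). All 20 cytosolic aminoacyl-tRNA synthetase genes were lower (median -1.14), as were all 8 genes of the CCT chaperonin (median -1.13), which folds actin and tubulin. Of 37 proteasome subunit genes 29 were lower and 0 higher (median -0.55). The synthetase, chaperonin and proteasome genes were not set against genes matched on length and GC content.

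Of 11 Toll-like receptor genes tested 10 were higher and 0 lower (median 2.71), and of 9 S100 genes 7 were higher and 0 lower (median 1.75). Of 25 genes with a Clec symbol, most of which encode C-type lectins, 14 were higher, 4 lower and 7 not called (median 1.28). Of 23 interleukin receptor chains 15 were higher, 4 lower and 4 not called (median 0.97). Of 22 integrin subunit genes 8 were higher, 0 lower and 14 not called (median 0.81). Of 16 subunit genes of the vacuolar proton pump 12 were higher and 0 lower (median 0.51, beside an upper 95% limit of 0.50 in random lists matched on base mean). Kinesin genes, with 12 higher and 4 lower of 31 (median 0.24), and serpin genes, with 6 higher and 1 lower of 19 (median 0.42), had medians within the central 95% of matched lists (-0.27 to 0.41 and -0.34 to 0.73). Tubulin genes had 4 higher, 4 lower and 6 not called of 14, and olfactory and vomeronasal receptor genes 1 higher, 1 lower and 6 not called of 8. Centring on the median fold change moves each of these medians by 0.02 on the log2 scale, and no family changes direction.

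Across the 12538 tested genes with a transcript length, length and log2 fold change had a Spearman rho of 0.248; genes are not independent replicates, and no p is given. Low members of the gene lists did not all follow the library with a size factor of 0.697. The 5 low members of the erythroid and megakaryocyte list had 43.0 normalised reads there, 3.20 and 3.95 in the others on its side, and 5.40, 9.20 and 19.1 in the libraries of the other side. For the 13 low lymphoid and NK members the values were 37.3 there, 13.3 and 15.8 on its side, and 30.6, 26.4 and 14.0 on the other. The 4 low interferon response members had 4.30 there, beside 19.7 and 1.98 on its side and 9.90, 3.45 and 1.28 on the other. The 15 low stromal and endothelial members had 24.4 there, 11.7 and 8.89 on its side, and 16.2, 10.3 and 10.2 on the other. The 3 low oestrogen receptor targets had 8.60 there, 4.80 and 3.95 on its side, and 3.60, 6.90 and 2.55 on the other.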
